A study of Mus musculus with 8 samples.

How the data were processed

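RNA from the submandibular gland, one of the major salivary glands, of 20-week-old male mice was measured on 8 one-colour microarrays, 4 from mice on normal chow (Ctrl) and 4 from mice with diet-induced obesity on a high-fat diet (DIO). The titles number the samples 1 to 4 within each group. Per the labels' protocols, total RNA was extracted with Trizol, ribosomal RNA was removed, and the remaining RNA was amplified with random primers into Cy3-labelled cRNA along the whole transcript. The arrays carry probes for long non-coding RNA (lncRNA) and messenger RNA.

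The authors deposited scanner output, with a file for each array. Per the file headers, the spots were read in a single channel and their fluorescence intensity was extracted with Agilent Feature Extraction, to which the submitters' processing notes give version 11.0.1.1. Per the file headers, the deposited processed intensity is background-subtracted and detrended within the array by that program and is not normalized between arrays. The deposited median intensity of each spot and of its local background is uncorrected. The other deposited columns used, per the file headers, are flags of 0 or 1 for spots well above background, significant over background, saturated or outlying. The header names a mouse build for the array design that differs from that of the gene table used for names, GRCm38.p6, so no coordinates are printed. Any normalization between arrays by the authors is not given in the sources used here.

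From these intensities, log2 of the processed signal was taken and each array's 75th percentile over all non-control spots was subtracted. All non-control spots entered the percentile because most of them were well above background. Control spots and spots marked as outliers were left out, and the spots of a probe were averaged on the log2 scale. A probe was tested if it was well above background on at least 4 of the 8 arrays and measured on at least 3 arrays of each group, which kept 54187 of 60823 probes. No spot was saturated.

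The groups were compared by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05 on the adjusted p. The files were read with version 1.17.8 of the data.table package, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Array-level measures were compared by exact two-sided permutation tests over the 70 assignments of 4 arrays to a group, whose smallest p is 0.0286. The labels do not say which animals the samples came from, so p-values measure the spread between these samples, which may be technical in part.

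An accession was given for 50 probes, each with 10 spots, and 46 of them matched a gene symbol in the gene table. The other probes have only the array maker's identifiers and were left unnamed. Probes were classed as non-coding where the identifier contains LNC or lincRNA or the accession is a RefSeq NR entry, as coding where it is a RefSeq NM entry, and otherwise as unclassified. Of 27 gene lists fixed before the data were examined, holding 578 genes, 4 had a measured member, with 6 genes in all, and none had the 5 members needed for camera or fry. Those list tests and the planned comparison of lncRNA and mRNA of the same locus were therefore not run. A list gene counts as measured only where a tested probe could be named, and the unnamed probes may hold others.

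The genes named were chosen by a rule fixed at the same time as the lists. Because no gene passed, it takes the 5 symbols with the smallest unadjusted p in each direction. It adds up to 3 members of each gene list by smallest p, and a fixed set of which only Cpt1a was measured. A gene that the rule also takes is not reported here. Rps4l, the only tested RefSeq non-coding entry, falls under the rule's non-coding part. Apoe, Chgb, Gsdmd, Actb, Gpi1, Prdx2, H2-Q7, H2-M2, Nup50, Hyal3, Olfr166 and Olfr1307 were chosen after their values were seen.

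The method was tested on simulated data with 200 changed probes among 54187, with the spread of the 8 arrays. It recovered 41.5% of 2-fold, 85% of 4-fold and 96% of 8-fold changes, with 3, 11 and 10 false calls. With the spread found without Ctrl array 2, it recovered 63%, 90.5% and 98.5%, with 8, 10 and 16 false calls. Alternatives covered quantile and cyclic loess normalization, the percentile over detected probes, normexp background correction with an offset of 50, the filter on dim probes, outlier spots, the replicate number as a block, trend and robust eBayes, array weights, other thresholds and leaving out each array in turn. Normexp was run on the median signal in place of the planned mean signal. A run without Ctrl array 2 and with quantile normalization was chosen after seeing the data.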

Results

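Transcript levels were measured in submandibular glands of male mice, with 4 samples from normal chow (Ctrl) and 4 from diet-induced obesity (DIO), to compare lncRNA and mRNA between the diets. Each sample was hybridised to 1 array, and the number of arrays limits the precision. The 75th percentile of the signal lay between 239.8 and 321 on the 8 arrays. On average 89.1% ± 3.35 (SD, n = 4) of the spots were well above background on the Ctrl arrays and 86.6% ± 3.88 (SD, n = 4) on the DIO arrays. These shares differed by less than the spread between arrays (exact permutation p = 0.343, two-sided), though the DIO array was lower than the Ctrl array of the same number in 4 of 4 cases.

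No transcript passed the threshold between DIO and Ctrl. Of the 578 list genes, 6 could be named, from the fatty acid oxidation, antioxidant, plasma cell and nerve lists. Other list members may lie among the unnamed probes, so these processes as a whole were not assessed. Among the 44 named genes tested, 21 were at a higher mean level in DIO and 23 at a lower one. For 38 of them the 95% interval of the difference lay within 2-fold in either direction. The exceptions were Kcnn2, Bambi, Duox1, Gsdmd, Chgb and Mzb1, whose intervals reached beyond 2-fold. Levels are log2 signals relative to the 75th percentile of the array, and differences are log2 DIO minus Ctrl.

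Of the fatty acid oxidation list, 3 of 29 genes had a named probe that was tested. None passed, either over all probes or adjusted over the list alone (smallest adjusted p = 0.622, limma). Cpt1a, whose product brings long-chain fatty acids into mitochondria, had a log2 level of 3.60 ± 0.21 (SD, n = 4) in Ctrl and 3.70 ± 0.10 (SD, n = 4) in DIO. Its difference of 0.10 had a 95% interval of -0.20 to 0.41, and its sign turned with cyclic loess normalization. Ppara, a nuclear receptor that activates genes of fatty acid oxidation, differed by -0.21 (95% interval -0.60 to 0.17). Acaa2, a thiolase of mitochondrial fatty acid oxidation, differed by 0.10 (95% interval -0.33 to 0.52), with the opposite sign under quantile and cyclic loess normalization and without Ctrl array 4 or DIO array 4. Each of the 3 intervals excludes a 2-fold difference. Pex11a, which acts in the division of peroxisomes and is named by its p rather than by a list, differed by 0.31 (95% interval -0.10 to 0.72), and by 0.18 to 0.43 when an array was left out. Over the same fits Cpt1a ranged from 0.01 to 0.16 and Ppara from -0.30 to -0.12.

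The antioxidant response, B and plasma cell, and Schwann cell and nerve lists each had a single measured member, and with all 8 arrays none passed, also when adjusted over the list alone. Gsta4, a glutathione transferase that detoxifies products of lipid peroxidation, differed by -0.06 (95% interval -0.47 to 0.35), with the opposite sign without Ctrl array 3. Mbp, a protein of myelin, differed by -0.25 (95% interval -0.73 to 0.23), and by -0.42 to -0.11 when an array was left out. Mzb1, an endoplasmic reticulum protein of B and plasma cells, had a log2 level of -0.15 ± 1.85 (SD, n = 4) in Ctrl and 0.41 ± 1.12 (SD, n = 4) in DIO. The highest and lowest arrays differed 14.7-fold for this gene. Ctrl array 2 stood at 2.62 and the other Ctrl arrays between -1.10 and -1.05, while DIO array 2 stood at -1.25 and the other DIO arrays between 0.82 and 1.15. The DIO level was 1.47-fold the Ctrl level (95% interval 0.359 to 6.05) with all arrays. Without Ctrl array 2 it was 2.80-fold (95% interval 1.21 to 6.48), which did not pass over all probes in limma (adjusted p = 0.941). Over the list alone this gene is the only measured member, so no adjustment applies and the limma p stays at its unadjusted 0.0222. An unadjusted p below 0.05 was reached in 1 of the 8 fits that left out an array, and the log2 difference lay between 0.25 and 1.48 in them.

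**Figure D1:**
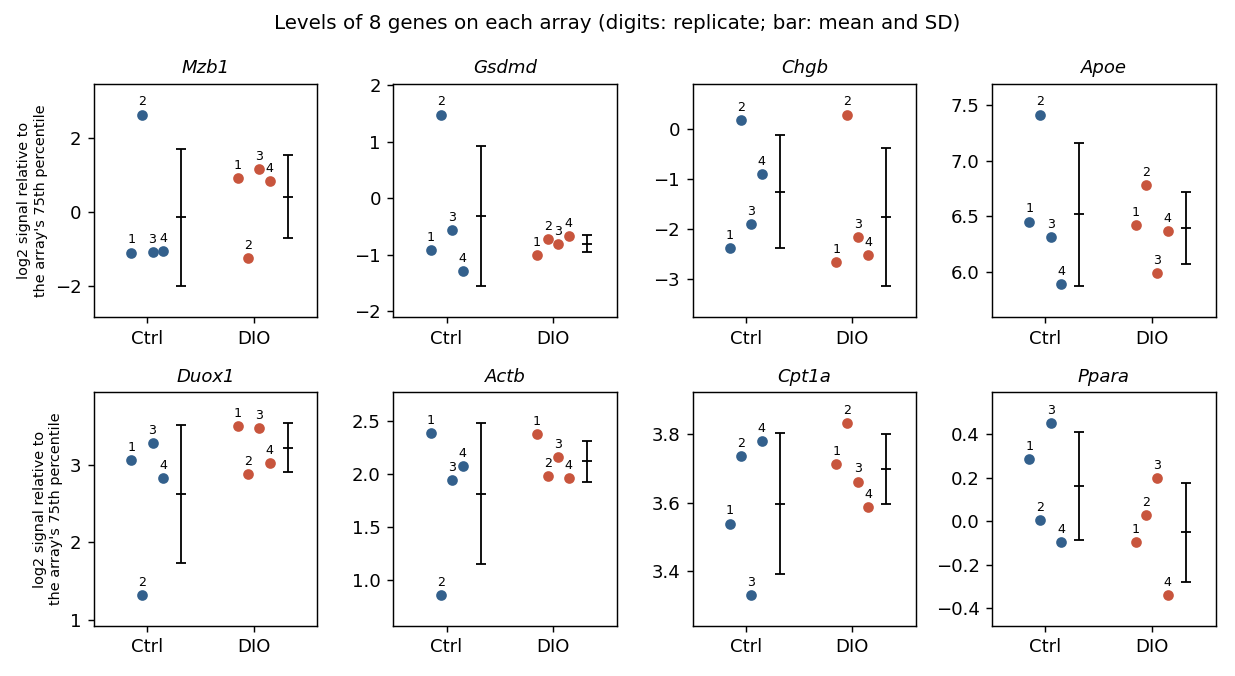
Level of 8 genes on each array, as log2 signal relative to the array's 75th percentile, with each point an array labelled by its replicate number and the bar giving the mean and SD of 4 arrays. Ctrl array 2 lies above the other Ctrl arrays for Mzb1, Gsdmd, Chgb and Apoe and below them for Duox1 and Actb.

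Of the genes with the smallest p, Lhfp alone had an unadjusted p below 0.05 with all 8 arrays and no block. With the replicate number as a block, the unadjusted limma p was 0.0110 for Lhfp and 0.0234 for Kcnn2. When an array was left out, it fell below 0.05 for Kcnn2 in 2 of 8 fits and for Pex11a and Il2 in 1 each. The Lhfp level was 0.74 ± 0.23 (SD, n = 4) in Ctrl and 0.35 ± 0.24 (SD, n = 4) in DIO. The difference of -0.40 (95% interval -0.78 to -0.02) had an unadjusted p of 0.0431 and an adjusted p of 0.774 in limma. Without Ctrl array 2 it was -0.29 (95% interval -0.64 to 0.06), and in 3 of the 8 fits that left out an array its unadjusted p was below 0.05. DIO array 2, at 0.70, lay within the Ctrl range of 0.56 to 1.07, and the other DIO arrays lay between 0.21 and 0.26. Each DIO array lay below the Ctrl array of the same number, though the labels do not say that the numbers pair the samples. Kcnn2, a calcium-activated potassium channel, differed by -0.75 (95% interval -1.66 to 0.15), by -0.35 with normexp, by -0.48 without Ctrl array 2 and by -0.99 without DIO array 2. Bambi, an inhibitory decoy receptor of TGF-beta signalling, differed by -0.53 with all arrays and by -0.19 without Ctrl array 2. Cav2, a caveolin of membrane pits, differed by -0.22, and Alkbh4, a demethylase, by -0.21 (-0.15 and -0.12 without Ctrl array 2). On the higher side, Duox1, an NADPH oxidase that produces hydrogen peroxide, differed by 0.60 with all arrays and by 0.16 without Ctrl array 2. Il2, a T cell cytokine, differed by 0.30 and Lhx1, a transcription factor, by 0.17 (0.20 and 0.10 without Ctrl array 2). The Il2 probe was dim, at -3.43 ± 0.28 (SD, n = 4) in Ctrl and -3.12 ± 0.25 (SD, n = 4) in DIO, and differed by 0.15 with normexp. None of these genes passed, and the smallest p adjusted over the accession probes alone was 0.708 (limma).

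**Figure D2:**
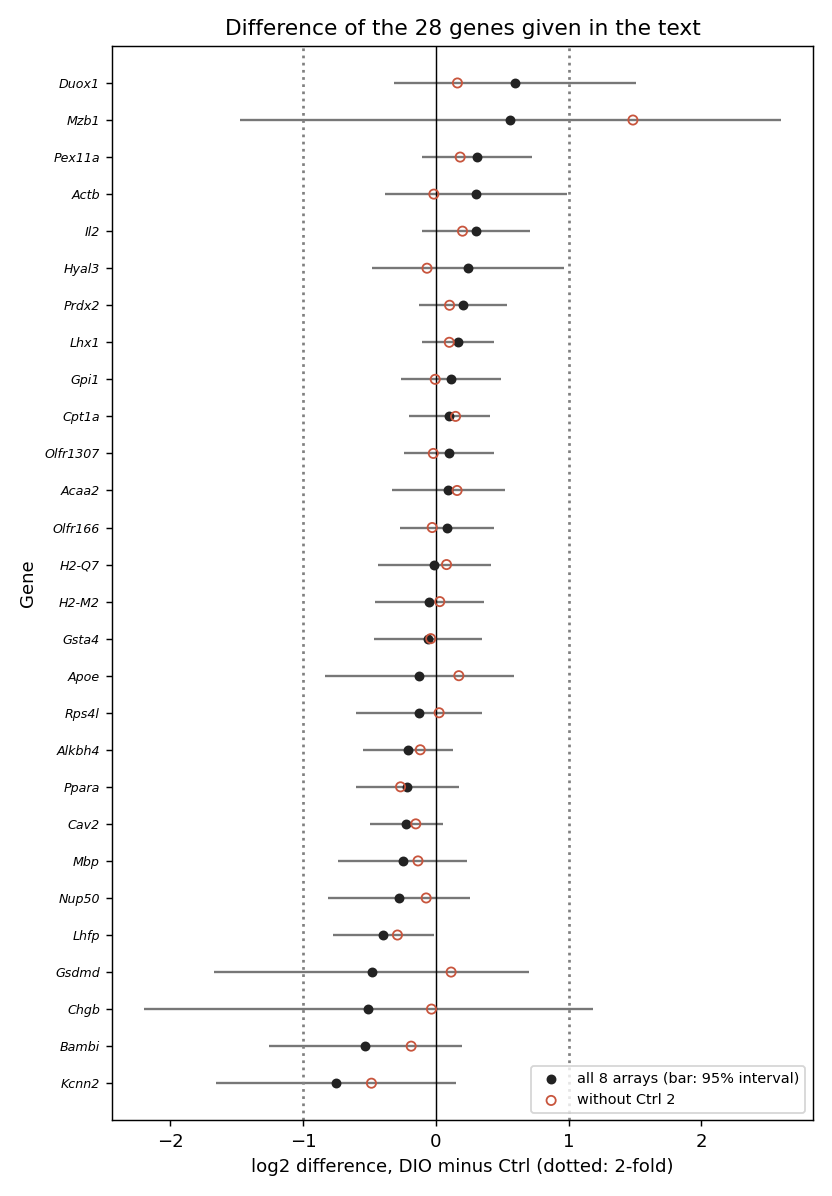
Difference of each of the 28 genes given in the text, as log2 DIO minus Ctrl on the horizontal axis, with filled points and 95% intervals from all 8 arrays and open points without Ctrl array 2. All but 6 intervals lie inside the dotted 2-fold lines, and Mzb1 has the widest interval, from -1.48 to 2.60.

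Among genes chosen after their values were seen, Gsdmd, which forms pores in pyroptosis, differed by -0.48 with all arrays and by 0.12 without Ctrl array 2. Apoe, a lipoprotein component, differed by -0.13 and by 0.17 without that array, and also turned sign without DIO array 3. Chgb, a protein of neuroendocrine secretory granules, differed by -0.51 (95% interval -2.20 to 1.18), by -0.03 without that array and by -1.19 without DIO array 2. The cytoskeletal gene Actb differed by 0.30 and by -0.01 without that array. The glycolytic enzyme gene Gpi1 differed by 0.12 (95% interval -0.26 to 0.49), with the opposite sign under quantile and cyclic loess normalization and without Ctrl array 2. Prdx2, which removes hydrogen peroxide, differed by 0.21 (95% interval -0.13 to 0.54), by 0.03 with quantile and 0.05 with cyclic loess normalization, and by 0.10 without Ctrl array 2. The class I histocompatibility genes H2-Q7 and H2-M2 differed by -0.01 and -0.05 (-0.21 and -0.22 with quantile normalization), with the opposite sign without Ctrl array 2, DIO array 2 or DIO array 4, and for H2-Q7 without Ctrl array 3. They share sequence with related genes that a probe may also bind. Rps4l, a transcribed pseudogene named by the fixed rule and not after its values, differed by -0.13 (95% interval -0.60 to 0.35), with the opposite sign without Ctrl array 2, and has the same limit. The remaining named genes lay between -0.28 (Nup50, -0.07 without Ctrl array 2) and 0.24 (Hyal3, with the opposite sign without Ctrl array 2).

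Ctrl array 2 stood apart from the other arrays. The first principal component held 49.7% of the variance and separated it from the rest, and 26.2% without it. Its correlation across probes with the other arrays was 0.941 to 0.958, against 0.981 to 0.990 among those arrays, where probes are not independent replicates. Within Ctrl, its level differed from the mean of the other arrays by 3.70 for Mzb1, 2.40 for Gsdmd, 1.90 for Chgb, 1.38 for Bambi, 1.20 for Apoe, -1.27 for Actb and -1.74 for Duox1. Of the 44 named genes, 10 lay over 2-fold from that mean.

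**Figure D3:**
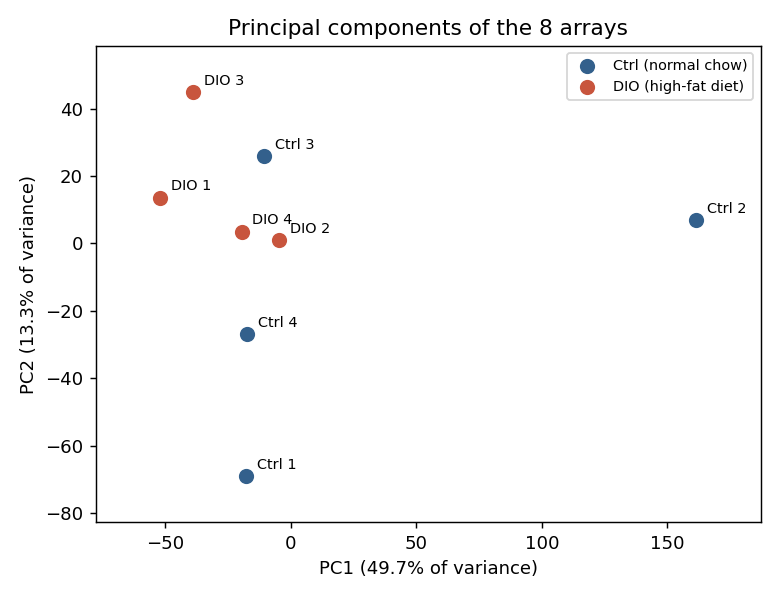
The 8 arrays on the first and second principal components of all tested probes, in arbitrary units, with Ctrl and DIO in different colours. Ctrl array 2 lies alone on the first component at 161, and the other arrays lie between -52.1 and -4.80 on it.

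Over all 54187 probes tested with limma, 0 passed and the smallest adjusted p was 0.774. An unadjusted p below 0.05 was found for 2441 probes (4.50%), of which 686 were higher and 1755 lower in DIO. Higher probes made up 28.1% of these, 46.6% with quantile normalization, 48.1% with cyclic loess, 19.5% with the percentile over detected probes, and 55.6% with normexp background correction. Of these probes, 66 were at least 2-fold higher and 103 at least 2-fold lower. These counts turned direction without Ctrl array 3 (531 higher, 171 lower), with the replicate block (190 and 151), with probes well above background on all arrays (76 and 49), with normexp (23 and 21) and with quantile normalization without Ctrl array 2 (46 and 35). All 4 DIO arrays lay above or below all 4 Ctrl arrays for 1550 probes (2.86%), and chance gives 2.86%. By direction, 500 probes (0.924%) lay above and 1050 (1.94%) below, where chance gives 1.43% each. These were counted with the 75th percentile scaling alone, where the median difference over all probes was -0.023. That median was 0.005 with quantile and 0.0006 with cyclic loess normalization, so the direction may depend on the scaling. The 95% interval lay within 2-fold in either direction for 83.4% of probes, and for 90.4% without Ctrl array 2.

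**Figure D4:**
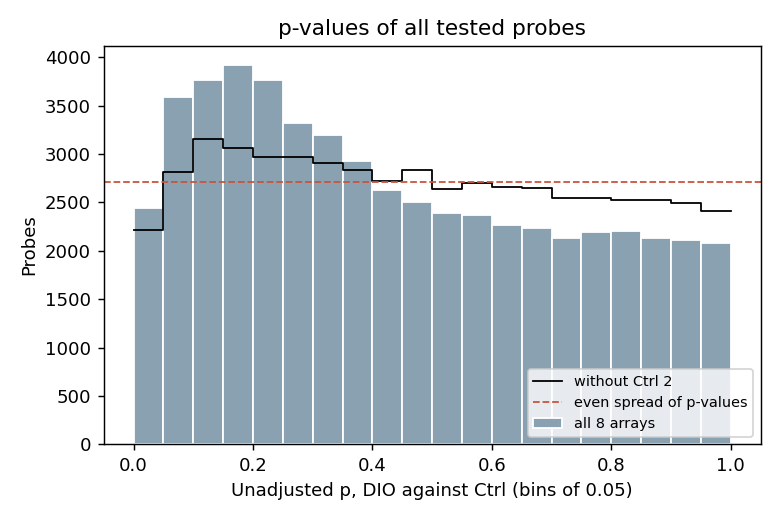
Number of tested probes by unadjusted p from limma, in bins of 0.05, for all 8 arrays (bars) and without Ctrl array 2 (line), with the even spread dashed. The lowest bin holds 2441 probes with all arrays and 2216 without Ctrl array 2, both under the even spread. The bins starting at 0.05, 0.1, 0.15 and 0.2 lie above it, with 3594, 3765, 3923 and 3769 probes for all arrays. Without Ctrl array 2 the same bins hold 2815, 3153, 3063 and 2974, a smaller excess. The bin starting at 0.95 holds 2082 and 2410. The p-values are thus not evenly spread, and the cause was not tested.

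The transcript classes gave the same count of 0. Among 26348 lncRNA probes tested, 328 were higher and 839 lower at an unadjusted p below 0.05 (4.43%). Among 27787 unclassified probes, 358 were higher and 915 lower (4.58%). The 43 coding probes with an accession held 1, Lhfp. The unnamed probes with the smallest p in each direction were ASMM10P014942V4 and ASMM10UP207V4, with differences of 1.14 and 1.11, and ASMM10AP1B102416192V4 and ASMM10LNC1A102389034V4, with -0.77 and -0.75. All 4 had an adjusted p of 0.774 in limma. Their mean log2 levels lay between -5.25 (ASMM10UP207V4 in Ctrl) and -2.15 (ASMM10P014942V4 in DIO). Gabrg1, well above background on 1 array only, lay at -5.11 in Ctrl and -5.37 in DIO. Probes named as negative were well above background in 55% of measurements, and 8 of 15 were among the tested probes. The background flag may therefore be lenient for dim probes, though it was not checked whether the probes named as negative bind a transcript.

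The Pgk1 control probes, which compare the 3′ with the 5′ part of the transcript, gave a log2 difference of 7.47 ± 0.12 (SD, n = 4) in Ctrl and 7.71 ± 0.08 (SD, n = 4) in DIO. All 4 DIO arrays were higher (exact permutation p = 0.0286, two-sided, the smallest possible, and 0.229 adjusted over 8 array measures). The first number of the array position goes with the group, so diet and position cannot be told apart in this difference. The same measure of Gapdh was 2.33 in both groups (exact permutation p = 1).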

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

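The tests on Ctrl array 2 were chosen after its deviation was seen, and the splits with the number as a block after the blocked count was seen. The other tests on same-numbered arrays and on other groupings were set before their values were known.

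Ctrl array 2 lay far from the other Ctrl arrays for Mzb1, at a log2 level of 2.62. By the same measure, Dixon's 95% critical value for the gap over the range, a single Ctrl array stood apart for 4177 of 54156 probes (7.71%), where chance gives about 1 in 20, and Ctrl array 2 was that array in 70.6%. A local defect is argued against, since the median SD between the 10 scattered spots of an accession probe was 0.703 times the highest of the other arrays. The largest shift of a block of spots was 0.07 (log2), within the 0.05 to 0.08 of the other arrays. The processed intensity is already detrended within the array, which may lower such shifts, so they decide little. A trend with brightness is argued against as the whole cause, since after cyclic loess the deviation had an SD of 0.768, against at most 0.460 on any other array. Tissue rich in B or plasma cells may have entered this sample. The rise of 3.70 rests on Mzb1 alone, the only measured member of that list. That source cannot be told apart from a difference between animals or in dissection, which was not tested. Control readouts also differed on this array. The control probe ERCC-00062_278 read 485, against 1123 to 2238 on the other arrays. The log2 difference of 3′ and 5′ probes was 7.28 for Pgk1, against 7.51 to 7.83, and 2.50 for Gapdh, against 2.15 to 2.39. Its share of spots well above background, 91.2%, matched that of Ctrl array 4. A technical difference of this sample or array was not tested and stays open.

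DIO array 2 lay far from the other DIO arrays for Mzb1 (-1.25, low), Lhfp (0.70, high) and Chgb (0.29, high). Of 48 accession probes, 3 stood apart in DIO, all on this array, and 2 in Ctrl, where chance gives about 1 in 20. Over all probes, a DIO array stood apart for 5.81%. It was DIO array 2 in 30.7% of these, DIO array 1 in 27.6%, DIO array 4 in 23.3% and DIO array 3 in 18.4%. DIO array 2 was thus the most frequent, but close to DIO array 1.

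Arrays with the same number deviated from their group means together, with a mean correlation across probes of 0.225 over the 4 numbers. Of the 24 ways to pair the arrays, 1, the real one, reached this mean and the highest other gave 0.132, which argues against chance. A position effect that follows probe brightness is argued against, since the mean was 0.221 after cyclic loess, which removes such trends. Position effects that do not follow brightness would remain after it and were not tested. Carry-over of Ctrl sample 2 into DIO array 2 could not be decided, as 66.9% of the probes raised 4-fold on the former were higher on the latter, between the limits set, and Mzb1 was low there. The median local background also went with the number, from 25 on Ctrl array 1 to 22 on Ctrl array 4. In DIO it went from 26 on array 1 to 21 on array 4. A shared position on the slide, which goes with the number, or shared handling may be the source and stays open.

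Other splits of the 8 arrays into 4 and 4 were counted. With a real count of 0 probes past the threshold, 35 of 35 splits must give at least as many, so that count decides nothing; the highest of the others gave 1. At an unadjusted p below 0.05 the real split gave 2441 probes, 10 of 35 splits gave as many, and the highest of the others, Ctrl arrays 1, 2 and 4 with DIO array 2 against the rest, gave 4986, so chance was not excluded for that count. With the number as a block the count was 4522, and of the 8 splits that keep the numbers together 1, the real one, gave as many. The highest of the others gave 2914, but 8 splits are too few for a share under 0.05.

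A signal appeared in control spots outside the comparisons. The probe ERCC-00062_278 had a median signal of 485 on its lowest array, Ctrl array 2, and of 1123 to 2238 on the other arrays. The array median of the negative control spots was at most 2.69. These control spots are not the probes named as negative, many of which were well above background.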

How the results depend on the processing

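The run without Ctrl array 2 and with quantile normalization and the normexp run on median signals were not planned beforehand. Neither were the counts at an unadjusted p below 0.05, the shares within 2-fold and the test over same-numbered arrays. No transcript, coding or non-coding, passed an adjusted p of 0.05 in limma under any setting run, and the smallest adjusted p was 0.216, without DIO array 2. An unadjusted p below 0.05 with a 2-fold difference took 169 probes, from 44 (normexp) to 702 (without Ctrl array 3) over the settings, and 341 with the replicate block. The count at an unadjusted p below 0.05 was 2441. Leaving out 1 array moved it to between 1321 (without DIO array 1) and 4396 (without Ctrl array 3), with 1613 without DIO array 3. With the replicate number as a block it was 4522, and still no probe passed. Nothing in the labels says that the numbers pair the samples, and the correlations of same-numbered deviations were 0.29, 0.30, 0.26 and 0.06, with 7 of 8 arrays correlating best with their own number, a hint from the data and not from the design. The cause of these moves was not tested. The difference in the share of spots well above background was -0.971 percentage points by the significance flag against -2.51, and -4.15 to -0.724 when 1 array was left out; an exact sign-flip test over same-numbered arrays gave p = 0.125, the smallest that 4 pairs allow. Over 28 named genes and 532 alternative values, 36 values in 14 genes changed sign and 19 values in 10 genes moved by over 1 standard error, none of them called; the smallest adjusted p of such a gene was 0.559. All arrays share 1 scan, so no further slide or scan block was run. The first number of the array position goes with the group, so it cannot be told apart from diet. List tests and same-locus comparisons were not run, for want of named probes. Dim probes are limited by a background flag that may be lenient.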

Other observations

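Some genes with restricted expression gave a signal on these arrays. The olfactory receptor genes Olfr166 and Olfr1307, chosen after their values were seen, were well above background on all 8 arrays, at log2 levels of 1.06 ± 0.27 and -0.28 ± 0.26 (SD, n = 4) in Ctrl and 1.15 ± 0.13 and -0.18 ± 0.10 (SD, n = 4) in DIO. Neither differed beyond the spread between arrays (limma adjusted p = 0.883 and 0.858). Olfactory receptors belong to a large family with related sequences, so the levels are uncertain. Tyr, the key enzyme of melanin synthesis, was not well above background on any array, and Gabrg1, a GABA receptor subunit, was so on 1 array.

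Ctrl array 2 held 768 probes at least 4-fold above every other Ctrl array and 137 at least 4-fold below. Its median deviation from the other Ctrl arrays was 0.29 among the dimmest probes and -0.49 among the brightest.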
